A study of Canis lupus familiaris with 3 samples.

How the data were processed

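The data are 3 two-colour hybridisations of human cDNA clone arrays with amplified RNA of dog MDCK cells, in which E47 transfectants were compared with MDCK-CMV control cells. Per the labels, the E47 RNA was labelled with Cy5 on the array of extraction 1 and with Cy3 or Cy5 on the 2 arrays of extraction 2, with the control RNA in the other dye. The design text gives RNA of control cells on each array, and from this the control was taken as a common reference. On that reading the test of the ratio against 0 leaves out the control's own spread.

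The values are log2 ratios as deposited by the authors, in 1 column per array. Their background correction, normalization, log base and direction are not given in the sources used here. The column medians were −0.0051, 0.0027 and 7.67e-04, so the columns look centred near 0. A log base of 10 was excluded because the largest value, 7.80, is above 4.82, which is the log10 of the range of a 16-bit scanner. Base 2 was used and the natural logarithm stays possible. The columns, the dye swap included, correlated positively, so all were taken to run the same way, and no sign was turned. That the ratio is E47 over control is likely, from the order of the channels in the labels and from the title, and is not stated. The array SD was 0.623, 0.430 and 0.535. Of 27648 spots 2111, 2366 and 2877 were empty on the 3 arrays. Signal intensities were not used here, so the signal over background of a spot is unknown and no filter on dim or control spots could be applied.

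Of the spots, 17488 carried 1 gene symbol in the platform annotation, 654 several and 9506 none. Symbols were kept as annotated. Of the 5508 genes tested, 5027 (91.3%) have the same symbol in the dog gene table of assembly UU_Cfam_GSD_1.0, which was used for names only. Human clones can bind related dog transcripts, so members of gene families cannot be separated. In all 9071 adjacent pairs of spots with an accession, both spots hold 1 clone. Over all adjacent pairs with values, those without an accession included, the values correlated with r = 0.933, 0.986 and 0.852 on the 3 arrays. Only the 23275 spots with a value on all 3 arrays were used. Spots of a gene were averaged per array, and spots with no symbol or several were tested one by one as 8500 unnamed features. Among the genes tested, 1040 had several clones, and in 401 of them the clones differed in sign. Of the 506 genes that passed, 121 had several clones and 16 had clones of opposite sign.

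The 2 arrays of extraction 2 share their RNA and were averaged, which leaves 2 replicates and 1 residual degree of freedom. The log2 ratios of all 14008 features were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior had 2.71 degrees of freedom, and the smallest adjusted p was 0.0194. Standard errors are those of the moderated fit. The test was tried on simulated data with variances drawn from the fitted prior. Of 14008 features, 100 were changed by 2-fold and 100 by 4-fold. The test called 58 and 93 of these, and 13 of 13808 unchanged features. The simulated errors were independent between genes. A dye effect was simulated only in the dye swap, where the average cancels it, and not in extraction 1. The simulation therefore cannot show how many false calls a dye effect or correlated genes would give. Figures were drawn with matplotlib 3.10.9.

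The 25 gene lists, the tests and the rule for the genes named were written before the data were examined. The rule takes TCF3 and CDH1, the 15 genes with the highest and the 15 with the lowest mean log2 ratio among those that passed and had the same sign on all 3 arrays, and of each list up to 6 members that passed, by size, or else the 2 with the largest ratio. Each list was tested with camera of limma, 2-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 25 lists. The result of 1 list is not reported here. With a correlation estimated from the data no list kept an adjusted p under 0.05. The estimate was above the preset value for E proteins and ID proteins, at 0.60, and for the epithelial list, at 0.04. It was below it for keratins at −0.07, cell cycle at −0.02 and interferon at 0.0018. These estimates rest on 1 residual degree of freedom. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction, without comparing them with other genes, gave an adjusted p of 0.0905 for the epithelial, cell cycle, mesenchymal and TGF-beta lists, 0.108 for keratins and 0.176 for the E protein and interferon lists.

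Alternatives changed the handling of replicates and dyes, the normalization, the level and filter of spots, the robust setting of eBayes and the threshold. For scaled arrays, centred values were divided by their median absolute value with normalizeMedianAbsValues, because the scale option of normalizeBetweenArrays gave no values on these ratios. Testing named genes alone, and reading the values as natural logarithms in the count of 2-fold genes, were added after seeing the data. No other column of values was left unused.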

Results

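RNA of MDCK cells, an epithelial line from dog kidney, was compared between transfectants carrying E47 and the MDCK-CMV control cells. E47 is a basic helix-loop-helix transcription factor encoded by TCF3 and is named in the series title as a repressor of E-cadherin, and the comparison addresses which transcripts differ when epithelial cells contain it. Each of 3 arrays of human cDNA clones held amplified RNA of E47 cells in 1 dye and RNA of control cells in the other. Extraction 1 was hybridised once, with E47 in Cy5, and extraction 2 was hybridised as a dye swap, once with E47 in Cy5 and once with E47 in Cy3. The dye swap was averaged, so n = 2 extractions. Of 27648 spots, the arrays gave a value for 25537, 25282 and 24771, in the order extraction 1, extraction 2 in Cy3 and extraction 2 in Cy5. After spots of a gene were averaged, 5508 named genes and 8500 unnamed features had a value on all 3 arrays. The number of arrays limits the precision of every value.

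E-cadherin, the adhesion protein of epithelial adherens junctions, had the second lowest mean among the genes that passed the test. Its gene CDH1 had a log2 ratio of −3.59 ± 0.09 (moderated SE, n = 2 extractions), which is 12.0-fold lower in E47 cells, with an adjusted p of 0.0194. The SE here and below is that of limma, moderated towards the spread of all features, so it can be smaller or larger than the spread of a gene between its own extractions. Spots, clones and the dye swap were averaged before the fit, so the SE leaves out the spread between them. The 3 arrays gave −3.52, −3.83 and −3.47. All ratios are stated as E47 over control. This direction is likely but not stated in the labels: every sample lists E47 cells as its first channel and control cells as its second, and the title names E47 as an E-cadherin repressor. If the deposited values ran the other way, every higher below would become lower. The base of the logarithm is not stated either and is read as 2, so fold values would be larger if it were the natural logarithm. A further CDH1 clone, which had no value on the Cy3 array and was left out, gave 0.23 and 0.19 on the other arrays; with it included, the CDH1 log2 ratio was −2.66.

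TCF3 itself was not higher in E47 cells. Its mean log2 ratio was −0.29 ± 0.08 (moderated SE, n = 2), with an adjusted p of 0.118, and it was below 0 on all 3 arrays. Whether its 2 human clones overlap the introduced cDNA is not given in the sources used here, so this value checks nothing about the introduced gene.

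In all, 506 of 5508 named genes (9.19%) passed the limma test at an adjusted p under 0.05, 294 of them higher and 212 lower in E47 cells. Of these, 502 had the same sign on all 3 arrays and 207 had a mean change of at least 2-fold, 124 higher and 83 lower. The size of the log2 ratio among the 506 genes ran from 0.54 to 3.81, with a median of 0.92. Without a test, 122 named genes changed by at least 2-fold in the same direction on every array, 75 higher and 47 lower, and 120 of these were among the 506. Both counts depend on the log base: read as natural logarithms, the values would put 400 of the 506 at a mean of at least 2-fold and 298 named genes at 2-fold on every array. A further 556 unnamed features passed the test. The count depended on which array of the dye swap was used: without the Cy5 array of extraction 2 it was 109, with 74 higher and 35 lower, and without its Cy3 array it was 919, with 448 higher and 471 lower. The excess of higher genes therefore turned with the array used, and at an unadjusted p under 0.05 there were 958 higher and 1005 lower genes. Of 117 genes picked by the naming rule, CDH1 and TCF3 aside, 68 lost their call without that Cy5 array. With scaled arrays 24 lost theirs. Only some of these losses are marked below, so a gene given without one did not necessarily keep its call. The p-values rest on the difference between 2 extractions, moderated towards the spread of all features. That difference also holds the dye effect of extraction 1, which has no dye swap. The extractions are not stated to come from separate cultures. With the control taken as a common reference, the p-values leave out its spread.

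**Figure D1:**
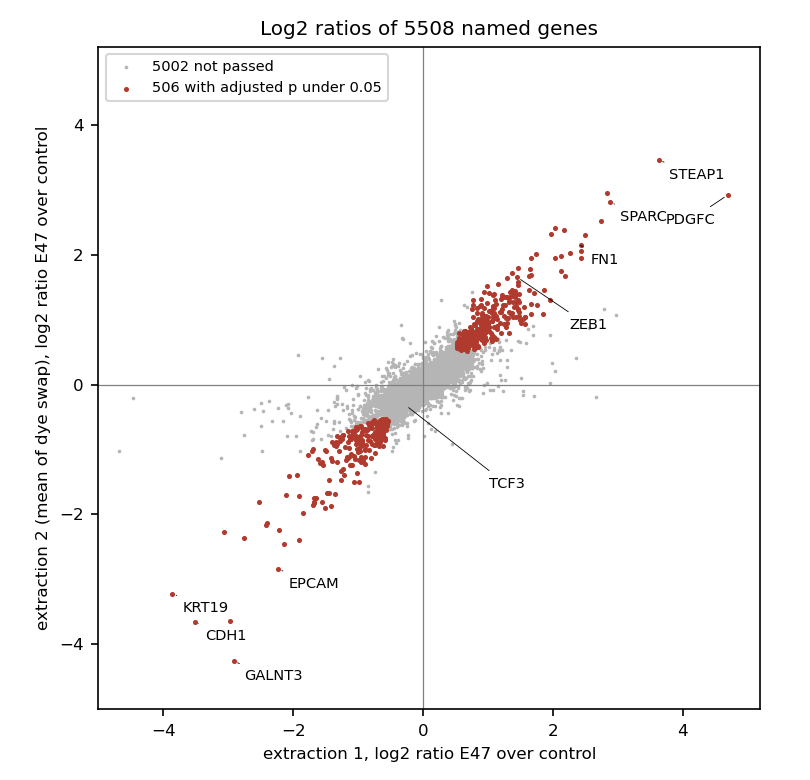
Log2 ratios of E47 over control cells for 5508 named genes, extraction 1 on the horizontal axis and the mean of the dye swap of extraction 2 on the vertical axis. The 506 genes with an adjusted p under 0.05 lie at both ends of the diagonal, with CDH1, KRT19 and GALNT3 at the low end and STEAP1 and PDGFC at the high end.

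The 15 genes with the highest ratios included secreted and membrane proteins. PDGFC, a platelet-derived growth factor, had a log2 ratio of 3.81 ± 1.26 (SD, n = 2 extractions), with array values between 2.32 and 4.70 and a moderated SE of 0.47. STEAP1, a transmembrane protein, was at 3.54 ± 0.09 (moderated SE, n = 2, as for the values that follow). It was measured by 1 spot, with 3.86 and 3.06 in the dye swap. TMSB4X, which encodes the actin-sequestering peptide thymosin beta-4, was at 2.90 ± 0.09, and the clone of its paralog TMSB4Y at 2.14. The dog gene table holds no TMSB4Y, and the closely related transcripts can bind both clones. SPARC, a secreted matricellular glycoprotein, was at 2.85 ± 0.09 and FN1, fibronectin, at 2.29 ± 0.11. The dye swap gave 3.24 and 2.38 for SPARC. GNG11, SCD5, ADGRL2, SCN9A, TIMP1, CALD1, GPC3, HTRA1 and SPRY2 lay between 2.64 and 1.99. TIMP1 encodes an inhibitor of matrix metalloproteinases and SPRY2 an inhibitor of receptor tyrosine kinase signalling. Adjusted p-values of these 15 genes ran from 0.0194 to 0.0349. PDGFC lost its call with robust eBayes, at an adjusted p of 0.0812, and without the Cy5 array of extraction 2.

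The 15 genes with the lowest ratios included CDH1 and other genes of epithelial cells. GALNT3, which starts mucin-type O-glycosylation, was at −3.59 ± 0.95 (SD, n = 2 extractions), with a moderated SE of 0.36. It lost its call with robust eBayes, at an adjusted p of 0.0584, and with scaled arrays, at 0.0637. KRT19, an epithelial keratin, was at −3.54 ± 0.19 (moderated SE, n = 2). F3, tissue factor, was at −3.31, and STARD10, a phospholipid transfer protein, at −2.67. KRT14 was at −2.57 and EPCAM, the epithelial cell adhesion molecule, at −2.54, with the EPCAM clones at −1.41 and −3.66. TIMP3, another metalloproteinase inhibitor, was at −2.30, opposite to TIMP1. ABLIM1, HERPUD1, RGS2, TFF1, TSPAN13, PTPRZ1 and MAP7 lay between −2.29 and −1.90. Adjusted p-values of the 15 lowest genes ran from 0.0194 to 0.0264, and each was below 0 on all 3 arrays. TSPAN13 lost its call with scaled arrays, at an adjusted p of 0.0502, and STARD10 and TFF1 lost theirs without the Cy5 array of extraction 2.

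Genes of epithelial junctions and polarity fell as a list. Of 25 measured genes, 9 fell, none rose and 16 did not pass; adjusted over the list alone, 17 fell and 2 rose. The median log2 ratio was −0.47, and 20 of the 25 were below 0 on every array. Beside CDH1 and EPCAM, the desmosomal linker DSP was at −1.16 ± 0.09 (moderated SE, n = 2), the tight junction proteins CLDN1 and CLDN4 at −1.16 and −0.92, and the protease inhibitor SPINT1 at −0.92. DSP was measured by 1 spot. CLDN4 lost its call with scaled arrays, at an adjusted p of 0.0573. Without the Cy5 array of extraction 2, CLDN1 and CLDN4 lost their calls, at adjusted p-values of 0.0682 and 0.0608. The camera test gave an adjusted p of 1.58e-06 with a preset correlation. As for the other lists, this p compares the list with other genes and takes genes as nearly independent. It is no measure of replication across extractions. With an estimated correlation, which here rests on 1 residual degree of freedom, the adjusted p = 0.759. CDH1 itself is a member of this list and also part of the basis for the direction.

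Of 8 measured genes of keratins, the intermediate filament proteins of epithelia, 5 fell, none rose and 3 did not pass, 1 of them above 0 on all 3 arrays, and adjusted over the list alone 6 fell. The median log2 ratio was −1.02, with KRT16 at −1.08 ± 0.10 (moderated SE, n = 2), KRT7 at −1.06 and KRT8 at −0.99 below the larger changes of KRT19 and KRT14. The camera adjusted p was 6.64e-04, and adjusted p = 0.759 with an estimated correlation.

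Mesenchymal and fibrillar matrix genes moved unevenly. Of 28 measured genes 8 rose and 1 fell, while 19 did not pass; adjusted over the list alone 9 rose and 2 fell. Besides SPARC, FN1 and the actin-binding protein CALD1 at 2.19 ± 0.15 (moderated SE, n = 2), the genes S100A4 at 1.55, VCAN, which encodes the proteoglycan versican, at 1.19 and the hyaluronan receptor CD44 at 0.96 rose. ENG, a TGF-beta co-receptor, fell to −0.94. The median of the list was 0.04 against a mean of 0.40, and the camera test gave an adjusted p of 0.214. N-cadherin, CDH2, chosen after its value was seen, was at 0.02 with an adjusted p of 0.892. In the basement membrane list, NID2 (nidogen-2) fell to −1.15 and the other 12 of 13 genes did not pass; adjusted over the list alone 1 gene rose and 1 fell, with a median of −0.08 and a camera adjusted p of 0.693.

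Among 7 measured transcription factors linked to the epithelial to mesenchymal transition, 2 rose and 2 fell, and adjusted over the list alone 2 rose and 4 fell. ZEB1, a zinc finger repressor of epithelial genes, was at 1.55 ± 0.10 (moderated SE, n = 2) and TWIST1, a helix-loop-helix factor, at 1.24 ± 0.13. KLF8 was at −0.78 and GATA6 at −0.73, and both lost their calls with scaled arrays, at adjusted p-values of 0.0673 and 0.0600. SNAI1, chosen after its value was seen, was at −0.45 with an adjusted p of 0.0696. The list median was −0.45, its mean 0.07 and its camera adjusted p 0.559.

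Of 10 measured genes in the list of E proteins and ID proteins, the dimer partners and inhibitors of factors such as E47, 6 rose, none fell and 4 did not pass, 2 of the 10 being below 0 on all 3 arrays, and adjusted over the list alone 6 rose and 1 fell. TCF4, the E protein that rose, was at 1.66 ± 0.13 (moderated SE, n = 2), with its clones at 2.83 and 0.49. The inhibitors ID1, ID4, ID3 and ID2 were at 1.28, 1.23, 1.09 and 1.08, and BHLHE40 at 0.74. The clones of ID2 ran from 0.67 to 1.83. When spots without a value on every array were kept, ID1 was at 0.53 with an adjusted p of 0.408. The list median was 0.91 and the camera adjusted p 0.0172, against adjusted p = 0.759 with an estimated correlation. With those spots kept, the adjusted p of the list was 0.0808, and from the Cy5 arrays alone it was 0.112.

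As a list, genes of S to M phase were higher in E47 cells. Of 40 measured genes 11 rose and none fell, and adjusted over the list alone 22 rose and 2 fell. The median log2 ratio was 0.35, and 31 genes were above 0 on every array. The mitotic kinase CDK1 was at 1.40 ± 0.08 (moderated SE, n = 2), TOP2A, a DNA topoisomerase, at 1.38, the spindle checkpoint genes BUB1B, MAD2L1 and BUB1 at 1.22, 1.00 and 0.91, and the spindle motor KIF11 at 1.17. The camera adjusted p was 4.52e-06, and adjusted p = 0.759 with an estimated correlation. Of 17 CDK inhibitors and p53 targets, SESN1 rose to 1.38, while GADD45A at −1.81, BTG1 at −1.18 and BAX at −0.94 fell. That list had a median of −0.04 and a camera adjusted p of 0.244, and adjusted over the list alone 2 genes rose and 6 fell.

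Interferon response genes had a median of −0.17, with −0.19 and −0.20 on the Cy5 arrays and −0.0656 on the Cy3 array, and a camera adjusted p of 0.0059, with adjusted p = 0.759 with an estimated correlation. Without extraction 1 the median was −0.11. Of 34 measured genes 2 fell, the same 2 when adjusted over the list alone, and none rose. They were HLA-B at −1.26 and HLA-E at −1.11, which encode class I antigen-presenting molecules rather than antiviral effectors. Human clones of this family can bind several dog class I transcripts, and the dog table holds neither symbol.

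**Figure D2:**
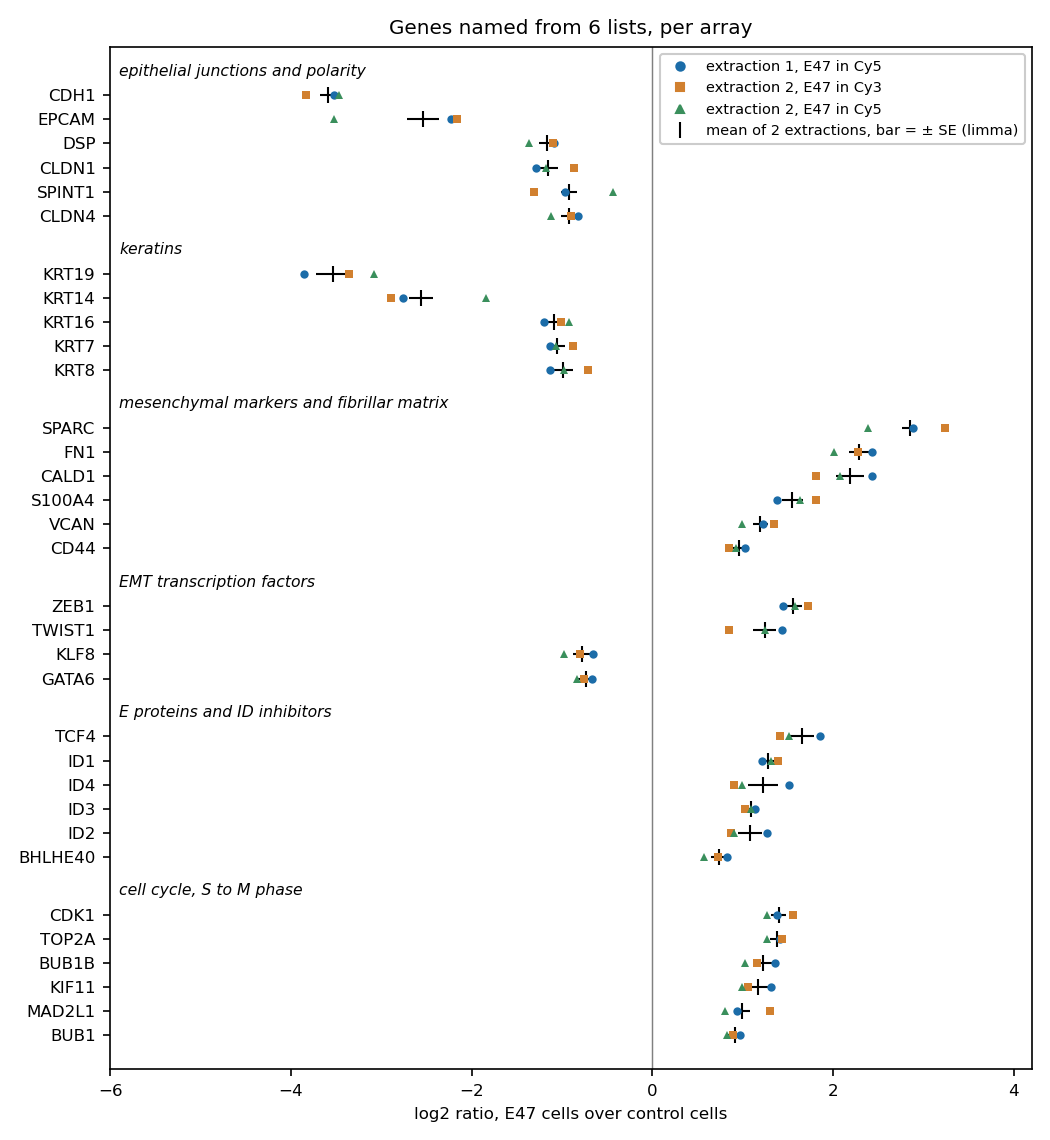
Log2 ratios of E47 over control cells for genes named from 6 lists, with 1 symbol per array and a vertical mark with its moderated SE for the mean of 2 extractions. Only members that passed the test are drawn, up to 6 per list by size, so the other members of each list are not shown. The epithelial and keratin genes drawn lie below 0 on all 3 arrays, down to CDH1 at −3.59. The matrix, E protein, ID and cell cycle genes drawn lie above 0, up to SPARC at 2.85. Of the transition factors drawn, ZEB1 and TWIST1 lie above 0 and KLF8 and GATA6 below.

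TGF-beta and BMP signalling genes included 7 that rose and none that fell among 32 measured, and adjusted over the list alone 12 rose and 3 fell. LTBP1, a latent TGF-beta binding protein, was at 1.22 ± 0.10 (moderated SE, n = 2), the signal transducer SMAD5 at 1.15, the receptor ACVR1 at 1.00, LTBP3 at 0.80 and SMAD2 at 0.71. The clones of LTBP1 were at 0.49 and 1.95. The clones of LTBP3 differed in sign, and the median over its spots was 1.39. The list median was 0.15 and its camera adjusted p 0.0954. In the Wnt list, the receptors FZD7 and FZD6 rose to 0.78 and 0.75 and none of 31 fell; adjusted over the list alone 3 rose and 3 fell, with a median of −0.09 and a camera adjusted p of 0.555. Among 34 growth factor receptors and ligands, EREG, an EGF family ligand, rose to 1.34, and FGFR4 and IGFBP7 to 0.58 and 0.55, while MST1R at −1.04 and EFNB1 at −0.74 fell. Clones of MST1R, FGFR4 and IGFBP7 differed in sign. FGFR4 and IGFBP7 lost their calls with scaled arrays, at adjusted p-values of 0.0576 and 0.0634, with spots that lack a value on an array kept, at 0.0558 and 0.0606, and without the Cy5 array of extraction 2, at 0.162 and 0.114, and their means were below 1.5-fold. IGFBP7 also lost its call with the median over spots and with median centring. MST1R lost its call with the median over spots, at 0.0603, and without the Cy5 array of extraction 2, and EFNB1 with scaled arrays and without that array. Adjusted over the list alone 3 rose and 3 fell, the median was −0.06 and the camera adjusted p 0.555. Among 22 angiogenic factors ENG alone passed, in both adjustments, with a list median of −0.08 and a camera adjusted p of 0.195.

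Extracellular proteases and their inhibitors changed in both directions, with 5 of 32 higher and 5 lower, and 9 higher and 5 lower adjusted over the list alone. MMP10, a stromelysin, was at 1.63 ± 0.12 (moderated SE, n = 2), the serpin SERPINE2 at 1.38 and the collagenase MMP8 at 1.16, while the transmembrane serine protease HPN fell to −1.43. With spots that lack a value on an array kept, MMP10 was at 1.07 with an adjusted p of 0.0976. The dog gene table does not hold the symbol MMP10, and human clones can bind related dog transcripts. The median was 0.02 and the camera adjusted p 0.559. Of 24 integrin and focal adhesion genes, ITGAV and ITGA7 rose to 1.22 and 0.94, and ITGB4 and ITGA2, integrin subunits of epithelia, fell to −0.81 and −0.65. Adjusted over the list alone 3 rose and 2 fell, with a median of −0.08 and a camera adjusted p of 0.562.

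Metabolic and stress genes also split. In the hypoxia and glycolysis list 4 of 19 rose and 3 fell: LDHA at 1.37, ENO1 at 1.06 and HIF1A at 0.93 were higher, and the glucose transporters SLC2A1 at −1.75 and SLC2A3 at −1.04 and the stress gene DDIT4 at −1.04 were lower. The clones of LDHA were at 0.80 and 1.94. Adjusted over the list alone 6 genes rose and 5 fell, with a median of 0.10 and a camera adjusted p of 0.559. Of 20 genes of the unfolded protein response and chaperones, CRYAB by 2.82-fold, DNAJA1 at 1.31 and HSPH1 at 0.96 rose, and HERPUD1 at −2.27, the transcription factor ATF4 at −1.69 and CALR at −1.02 were among 4 that fell. Adjusted over the list alone 3 rose and 5 fell, with a median of −0.15 and a camera adjusted p of 0.224. Of 26 apoptosis regulators, CYCS, cytochrome c, rose to 1.67 and DAPK1 to 0.66, and CASP6 at −1.01, BAX, and TNFSF10 at −0.58 fell, with the same counts over the list alone. Clones of DAPK1 differed in sign. TNFSF10, CASP6 and DAPK1 lost their calls with spots that lack a value on an array kept, at adjusted p-values of 0.0552, 0.0574 and 0.0635. The median was −0.12 and the camera adjusted p 0.299.

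Of 26 cytosolic ribosomal protein genes 3 rose and 5 fell, with RPL8 at −1.35, RPS9 at −1.07, RPL28 at −1.02, RPL10 at −0.86 and RPS19 at −0.80 lower and RPS13 at 0.80 higher. RPL8 lost its call with robust eBayes, at an adjusted p of 0.0553. Adjusted over the list alone 4 rose and 9 fell. The median was −0.23, with −0.50 on the array of extraction 1 and 0.02 on the Cy3 array, and the camera adjusted p was 0.195. Among 23 proteasome subunits PSMA2 at 1.25, PSMD12 at 0.91 and PSMC2 at 0.90 rose and none fell; adjusted over the list alone 6 rose and 1 fell, with a median of 0.13 and a camera adjusted p of 0.294. COX7A2 at 1.00 and NDUFB3 at 0.57 rose among 16 respiratory chain genes, where 5 rose and 2 fell adjusted over the list alone, with a median of 0.08 and a camera adjusted p of 0.741. Both lost their calls with scaled arrays, at adjusted p-values of 0.0784 and 0.0677, and with quantile normalization, at 0.0523 and 0.0502. The dog gene table does not hold the symbol COX7A2. Of 5 cholesterol and fatty acid synthesis genes SREBF1 fell to −0.91, with 0.14 on the Cy3 array, in both adjustments. Without the Cy5 array of extraction 2 it was at −0.47 with an adjusted p of 0.511, and with a dye term at −0.61 with an adjusted p of 0.0952. The median was −0.12 and the camera adjusted p 0.299.

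Markers of blood cells and of renal tubule transport were measured too. Of 25 lymphocyte and myeloid genes only PTPRC, the CD45 phosphatase, passed, rising to 1.03 ± 0.10 (moderated SE, n = 2), in both adjustments. It was measured by 1 spot. The list median was −0.0012 and the camera adjusted p 0.946. Of 8 genes of renal tubule transport, the water channel AQP3 fell to −1.56 and the sodium pump subunit ATP1B1 rose to 0.87, also in both adjustments. ATP1B1 lost its call with scaled arrays, at an adjusted p of 0.0576, and without the Cy5 array of extraction 2, at 0.0744. The median was −0.10 and the camera adjusted p 0.555.

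**Figure D3:**
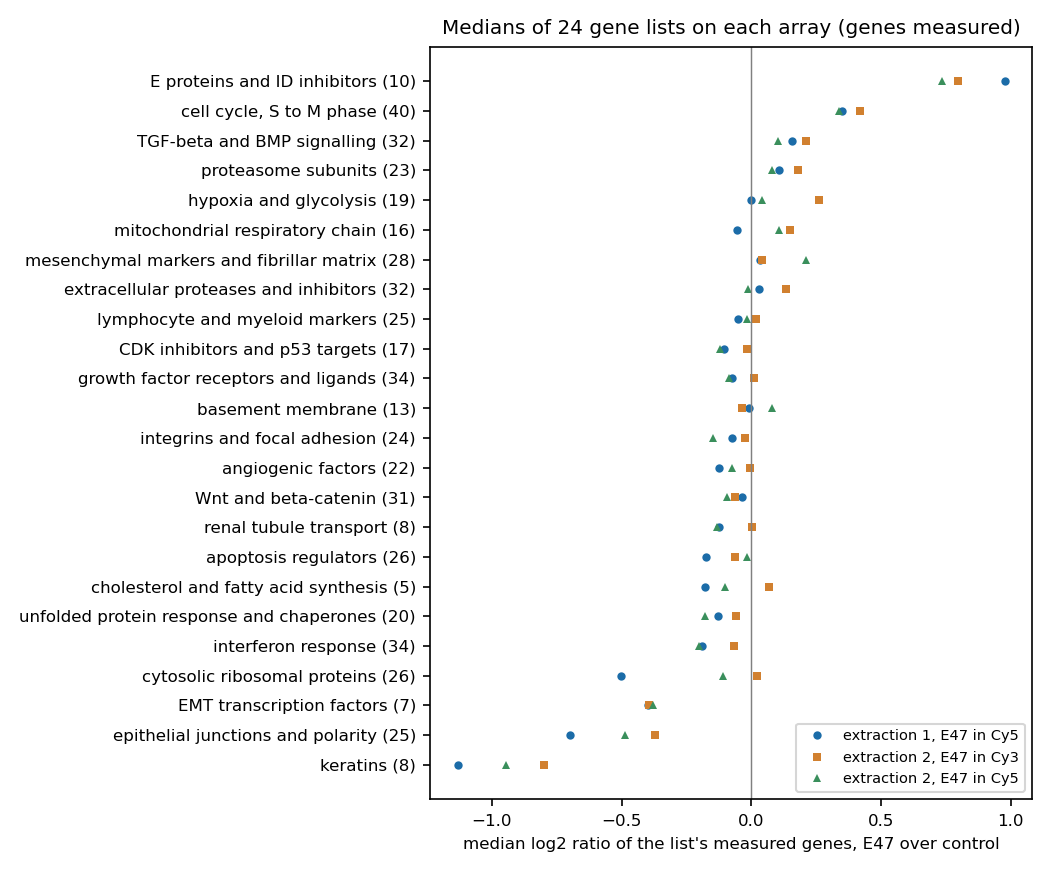
Median log2 ratio of each of 24 gene lists on each of the 3 arrays, with the number of genes measured in parentheses. Over the extractions keratins and epithelial genes lie lowest, with medians of −1.02 and −0.47, and E proteins with ID proteins highest at 0.91. The transition factors are close to the epithelial genes at −0.45. On the Cy3 array they lie below them, at −0.39 against −0.37.

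Across the 5508 named genes the ratios of extraction 1 and the mean of extraction 2 correlated with Pearson r = 0.827 and a Spearman correlation of 0.825, and 82.4% of genes had the same sign. Genes are not independent replicates, so no p is given. The 2 arrays with E47 in Cy5, of different extractions, correlated with r = 0.851, while the dye swap of extraction 2 correlated with r = 0.764 and the Cy3 array with extraction 1 at r = 0.694. The dye effect, taken as the difference within the dye swap over 2, had an SD of 0.157 across genes, against 0.468 for the mean E47 effect. The difference within the swap also holds the noise of its arrays. The difference between the extractions over 2 had an SD of 0.157 as well. Extraction 1 has no dye swap, so the dye effect stays in its values. In 10 genes the dye swap gave opposite signs with a size over 0.5 on both arrays.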

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

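Testing named genes alone and reading the values as natural logarithms were chosen only after the results were seen. All 506 genes kept their sign under the alternatives in which they were tested. The alternatives use the same 3 arrays, on which 502 of the 506 had 1 sign throughout, so this was largely set beforehand. Of 117 named genes, 49 kept their call with the dye-balanced pair (extraction 1 and the Cy3 array) and 93 with scaled arrays. With robust eBayes 114 kept it. All 117 kept it with single spots, where 1 passing spot of a gene was enough. CDH1, which kept its call throughout, and TCF3, which had none, are not among the 117. Genes changed, higher and lower were 109, 74 and 35 with the dye-balanced pair and 919, 448 and 471 with the Cy5 pair. A dye term gave 743, 424 and 319, and 479 of the 743 were among the 506. The counts were 1008, 560 and 448 with 3 arrays as replicates, and 935, 508 and 431 with single spots. With single spots a gene counted in each direction in which at least 1 of its spots passed. At an adjusted p under 0.10 they were 1244, 653 and 591, and with named genes alone 1175, 624 and 551. By design, a dye effect enters the residual of the dye-balanced pair and stays in the mean of the Cy5 pair. How far this sets the counts was not tested, nor was any other cause. A fit with extraction as a random block was not run, since duplicateCorrelation could not be fitted to 3 arrays. Genes at least 2-fold on all arrays numbered 189 as single spots, where 1 such spot per gene was enough. They numbered 384 at 1.5-fold, 35 at 3-fold and 298 with values read as natural logarithms, which lowers the 2-fold limit. Agreement in sign was 71.5% and 83.8% in the dye-balanced and Cy5 pairs and 81.2% and 81.3% after scaling and quantile normalization. Neither fry nor an estimated correlation kept a call for lists at medians of −0.47 (epithelial), −1.02 (keratins), 0.91 (E proteins and ID), 0.35 (cell cycle) and −0.17 (interferon). E proteins and ID lost their call with the looser filter (0.64) and the Cy5 pair (0.89). The test's direction turned for transition factors with the looser filter (−0.15), integrins with single spots (0.0701), and lymphocyte (−0.0318) and respiratory chain lists (0.0736) with the Cy5 pair. From single extractions, medians ranged from −0.70 to −0.44 (epithelial), −0.41 to −0.40 (transition factors), 0.35 to 0.42 (cell cycle), −0.19 to −0.11 (interferon), 0.0317 to 0.0815 (mesenchymal), −1.13 to −0.91 (keratins) and 0.77 to 0.98 (E proteins and ID). For none of these was the cause tested. Signal over background is unknown, so its effect is open.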

Other observations

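Tests of noise on the Cy3 array and of dye bias in the amino acid response and cell cycle genes were chosen only after the values they use had been seen; the other tests were written before.

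Genes of the amino acid response, which the transcription factor ATF4 drives when amino acids are short, formed a group not described above. After ATF4 and 7 genes linked to it had been seen among the results, 6 of these 8 as members of the fixed lists, with ASNS, asparagine synthetase, at −1.71, MTHFD2, a mitochondrial folate enzyme, at −1.68, ATF4 at −1.69 and GADD45A at −1.81 among 7 that fell and VEGFA at −0.75 (adjusted p 0.0851) not passing, a list of 36 further genes was written, of which 18 had been measured. Of these 18, 5 fell, 1 rose and 14 were below 0. The serine synthesis enzyme PSAT1 was at −1.17, CTH at −1.10, the amino acid transporter SLC1A5 at −0.96, CEBPG at −0.92 and WARS1 at −0.90, while VLDLR rose to 0.75. Their median was −0.32, at percentile 0.0200 of 10000 random lists of the same size. This describes these arrays and is no p across replicates. The values go with the hypothesis that other genes of the response fall too, although 12 of the 18 did not pass the test. Dye bias stays open for these 18 genes: their median was −0.21 on the Cy3 array (bootstrap 95% interval over genes −0.57 to 0.0641), against −0.37 and −0.27 on the Cy5 arrays. The 8 genes seen first had a median of −1.38 on the Cy3 array and −1.60 and −1.77 on the Cy5 arrays, and the 5 further genes that fell lay between −0.87 and −1.20 on the Cy3 array, but these genes are known by their low mean, so their values do not decide it. Whether the state of the control cells contributed was not tested, and no biological explanation was tested.

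The higher S to M phase genes were also set against dye bias. Their median of 0.42 on the Cy3 array (bootstrap 95% interval over genes 0.27 to 0.61), against 0.35 and 0.34 on the Cy5 arrays, argues against it as the whole source. A difference in culture density or growth state between E47 and control cells stays open, because the spread of the control was not measured and no measure of growth was used here.

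Arrays of the same dye orientation but of different extractions correlated more (r = 0.851) than the dye swap of the same RNA (r = 0.764). If a dye bias of each clone were the source, the dye difference of a clone printed at 2 separate places would correlate. For 803 such clones r was 0.252 (95% interval 0.186 to 0.316), between the bounds of 0.3 and 0.1 set beforehand. The plain mean of the 3 arrays, 2 of them with E47 in Cy5, correlated with r = 0.757 between the places. That mean holds part of the dye difference and averages more arrays than it, so the r values are not measured alike. A bias from the position on the slide would make different clones at neighbouring spots correlate, and for 5331 neighbours r was 0.111 (0.0845 to 0.138), which also decides nothing. More noise between adjacent spots on the Cy3 array is argued against by their correlation of 0.986, the highest of the 3 arrays. Adjacent spots share a place on the slide, so noise over a region or over the whole array is not covered. A clone bias and a position effect may both contribute and cannot be told apart from these values.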
